A study of Homo sapiens with 12 samples.

How the data were processed

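The samples were chromatin immunoprecipitation sequencing (ChIP-seq) libraries from HEK 293T cells, a human embryonic kidney line that carries the SV40 large T antigen. Per the labels, the cells were transfected and collected after 3 days, chromatin was sonicated to an average of about 300 bp, and HA-tagged dCas9 was precipitated with an antibody against the HA epitope tag. Libraries were prepared from 1 to 5 ng of precipitated DNA, and fragments of 300 to 650 bp were taken from a gel. dCas9 is a Cas9 protein that binds DNA without cutting it, and a single guide RNA (sgRNA) directs it to sites that match the guide next to a short protospacer adjacent motif. Peak lists of 9 libraries were analysed, covering 6 guides. sgRNA1, sgRNA2 and sgRNA3 had 2 replicates each, and sgRNA4, sgRNA5 and sgRNA6 had 1 library each. Of the 12 samples described, the other 3 (dCas9 without sgRNA, and amplicons from cells with wild-type Cas9 with or without sgRNA) were not analysed here. Values could therefore not be set beside a background measured without a guide.

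Each deposited list gave the chromosome, start, end, name and score of every peak. The submitters' processing notes name Bowtie, Bowtie2 and MACS, with no version, and the genome build hg19; alignment and calling settings are not given in the sources used here. The score is the authors' value per peak, deposited as MACS gave it; no score lay below 50 in any list. Scores depend on the read depth of their own library and were used only to describe, rank or filter peaks within 1 list. Peaks had been called for each library separately, so replicates were compared by overlap. The lists hold no read counts, so the depth per library is unknown and so is its effect on the number of peaks. Nothing in the labels says that replicates came from separate cultures, so a p-value between libraries measures only the spread between these libraries, which may be technical.

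Coordinates are given for hg19 and counted from 1. No genome or gene annotation of that build was used here, so peaks are named by position. Peaks were called overlapping when they shared at least 1 bp. The replicates of a guide were merged into 1 list for comparisons between guides. In the placement test, a permutation test of peak positions, chance overlap was the mean over 1000 random placements of peaks on their own chromosomes, each chromosome taken to end at the last peak of any list; the smallest p that these placements can give is 0.000999, one-sided. Shares carry exact binomial (Clopper-Pearson) 95% intervals, which cover counting error only. Peak numbers of the 3 replicated guides were compared by an exact permutation test on log10 counts. Overlap with a guide's own replicate was set against overlap with the replicate 2 lists of the other guides by two-sided Fisher's exact tests, adjusted by Benjamini-Hochberg over 6 tests, and overlap of the 15 pairs of guides was adjusted over those 15. Peaks per chromosome were tested against chromosome length by a chi-square test whose exact p was estimated from 100000 simulated draws over 23 chromosomes, without Y; unsequenced gaps, planned to be left out, were not removed. In all tests of overlap, score and chromosome the units were peaks, which are not replicates, so these p-values describe the lists at hand.

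The named regions were fixed by a rule made before the data were examined. The rule took, for each guide, the 5 peaks with the highest score. For guides with replicates these were the 5 highest replicate 2 peaks that overlapped a replicate 1 peak. It then took the 10 regions found with the most guides, ties broken by mean rank. Alternatives fixed beforehand were an overlap of at least 50% of both peaks, centres within 500 bp, the 50% of each list with the higher scores, peaks within 1000 bp merged, leaving out either replicate, only peaks found in both replicates, only peaks not shared with another guide, covered length in place of peak number, peak width in place of score, and the replicate number as a block. Chosen after the data were seen were random shifts of 10 to 50 kb, random placement inside 1 Mb bins that hold a peak, the exact McNemar test in place of Fisher's test, and the stricter overlap and score settings for comparing a guide's own list with those of other guides. Searches for a seed sequence and its adjacent motif, match length, promoter shares and gene lists had been planned and were not run.

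The placement test was tested on simulated data. It used 50 pairs of lists the size of sgRNA2 replicate 1 (58 peaks) and sgRNA3 replicate 2, placed at random, with fewer placements than for the data. It called 50 of 50 pairs with 6 planted shared peaks and 0 of 50 without. Random lists of this size rarely overlap and do not cluster as real peaks may. The simulation therefore checks that the code works, and not the error rate on the real lists. Overlap calls were checked by brute force, with 0 of 174 wrong. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.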

Results

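Sites occupied by dCas9 with 6 different guides were mapped by HA ChIP-seq in HEK 293T cells, to ask where in the genome each sgRNA brings the protein besides its intended target. The 9 peak lists held between 41 and 33611 peaks. sgRNA1, sgRNA2 and sgRNA3 were each represented by 2 replicates, and sgRNA4, sgRNA5 and sgRNA6 by 1 library each, so values for the latter carry no replicate error. Read depth is unknown for all 9 libraries.

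The lists differed widely in the number of peaks. With sgRNA6, 33611 peaks covered 25.15 Mb, with sgRNA4 13660 peaks covered 11.2 Mb, and with sgRNA5 8346 peaks covered 5.88 Mb. The sgRNA1 lists held 96 peaks (0.0477 Mb) in replicate 1 and 1278 (1.01 Mb) in replicate 2, those of sgRNA2 58 (0.0377 Mb) and 570 (0.520 Mb), and those of sgRNA3 41 (0.0203 Mb) and 382 (0.286 Mb). Median peak width lay between 463 bp in sgRNA1 replicate 1 and 820.5 bp in sgRNA2 replicate 2.

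The replicate 2 list was longer than the replicate 1 list by 13.3 times for sgRNA1, 9.83 times for sgRNA2 and 9.32 times for sgRNA3. On the log10 scale the counts were 2.54 ± 0.795 for sgRNA1, 2.26 ± 0.702 for sgRNA2 and 2.10 ± 0.685 for sgRNA3 (SD, n = 2 each). The difference among these guides was smaller than the spread between replicates (exact permutation test, p = 0.667; the smallest p that the 15 arrangements allow is 0.0667). That spread includes the length difference between replicates 1 and 2, which all 3 guides showed. With the replicate number as a block, exact permutation gave p = 0.167, the smallest that 6 arrangements allow. The order of the guides, sgRNA1 above sgRNA2 above sgRNA3, was the same in both replicates. Numbers for sgRNA4, sgRNA5 and sgRNA6 were not tested.

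**Figure D1:**
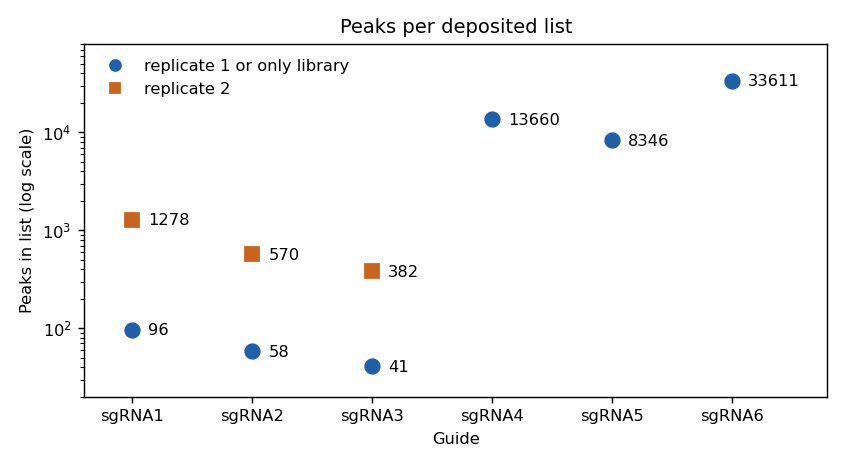
Number of peaks in each of the 9 lists (log axis) by guide, 1 point per library, with circles for replicate 1 or the only library and squares for replicate 2. Replicate 2 lies above replicate 1 for all 3 replicated guides, and the single libraries of sgRNA4, sgRNA5 and sgRNA6 hold 13660, 8346 and 33611 peaks.

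For each replicated guide, the highest replicate 1 peak was found in both replicates and with no other guide. With sgRNA1 it lay on chromosome 9 at 110103257 to 110104060, with a score of 799 (rank 1) in replicate 1 and 1111 (rank 2) in replicate 2. With sgRNA2 it lay on chromosome 5 at 87240329 to 87241045, with 988 (rank 1) in replicate 1 and 146 (rank 5) in replicate 2. With sgRNA3 it lay on chromosome 9 at 110184226 to 110184963, with 1169 (rank 1) in replicate 1 and 517 (rank 2) in replicate 2. The sgRNA1 and sgRNA3 peaks on chromosome 9 were 80.2 kb apart. The intended targets of the guides were not analysed here, so these peaks may be on-target sites. The highest score of a list lay between 753 (sgRNA2 replicate 2, median 59.5) and 3159.7 (sgRNA6, median 90.0). No list held a score below 50, which places the medians near that floor, so ratios of scores are not meaningful. By width, the widest peak was 2.08 to 10.9 times the median of its list.

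Further high peaks of sgRNA1 found in both replicates and with no other guide lay on chromosome 17 at 17401587 to 17402225 (score 565 in replicate 2), on chromosome 14 at 105521475 to 105522275 (406) and on chromosome 14 at 93611483 to 93611831 (324). In sgRNA2, the other peaks taken by the rule for named regions were shared: that on chromosome 1 at 144931421 to 144932756 (183) with all 5 other guides, that on chromosome 14 at 93259933 to 93261101 (168) with 3, and that on chromosome 2 at 182756706 to 182757607 (93.2) with 4. The chromosome 2 peak ranked only 34 of 570 in replicate 2. In sgRNA3, the peak on chromosome 4 at 1749741 to 1750783 (202) was shared with 2 guides and that on chromosome 4 at 7364979 to 7365842 (111) with 1, whereas that on chromosome 8 at 143407096 to 143407716 (106) was found with sgRNA3 alone.

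The highest sgRNA4 peak lay on chromosome 19 at 1768687 to 1769547 (score 2436), followed by peaks on chromosome 22 at 49661256 to 49662514 (2254), chromosome 5 at 1229490 to 1230702 (2129.6), chromosome 16 at 57601798 to 57604251 (1901) and chromosome X at 1743071 to 1744293 (1773). Of these only the chromosome 5 peak overlapped a peak of another guide, one of score 64.0 and rank 25419 with sgRNA6. With sgRNA6, the highest peaks lay on chromosome 14 at 103528706 to 103529484 (3159.7), chromosome 7 at 101860671 to 101861600 (3128) and at 148313428 to 148314680 (3121), chromosome 15 at 101094140 to 101099182 and chromosome 4 at 699233 to 700925. The last 2 scored exactly 3100, as did 3 further sgRNA6 peaks. A value repeated exactly may be a ceiling of the score. The order of these peaks, also against those scored above 3100, is therefore not resolved. The chromosome 15 peak overlapped a sgRNA4 peak of score 56.0, and the other 4 overlapped no peak of another guide. With sgRNA5, 4 of the 5 highest peaks were shared. Its peak on chromosome 17 at 46178032 to 46179159 scored 1888 and overlapped peaks of sgRNA4 (98.8) and sgRNA6 (181). Its peak on chromosome 10 at 3356000 to 3357628 scored 1734 (rank 3) and overlapped a sgRNA6 peak of score 1797 (rank 36) and peaks in both sgRNA3 replicates (67.0 and 88.4). Its peak on chromosome 14 at 105742053 to 105744051 scored 1211 and overlapped a sgRNA4 peak of score 50.5. The peak on chromosome 14 at 102038080 to 102039174 (1102) was found with sgRNA5 alone. When 50% of both peaks had to overlap, or when the 50% of each list with the higher scores was used, no other guide was left under both settings at the sgRNA5 peak at 105742053 and the sgRNA6 peak on chromosome 15, and under 1 of them at the sgRNA3 peaks on chromosome 4 and the sgRNA4 peak on chromosome 5.

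One region, on chromosome 15 at 68132053 to 68133278, held a peak in all 9 lists. It ranked first in replicate 2 of sgRNA1 (score 1199), sgRNA2 (753) and sgRNA3 (1339) and with sgRNA5 (2319). In replicate 1 it ranked 2 for sgRNA1 (607), 2 for sgRNA2 (409) and 3 for sgRNA3 (348). It ranked 59 with sgRNA4 (602) and 109 with sgRNA6 (1065).

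**Figure D2:**
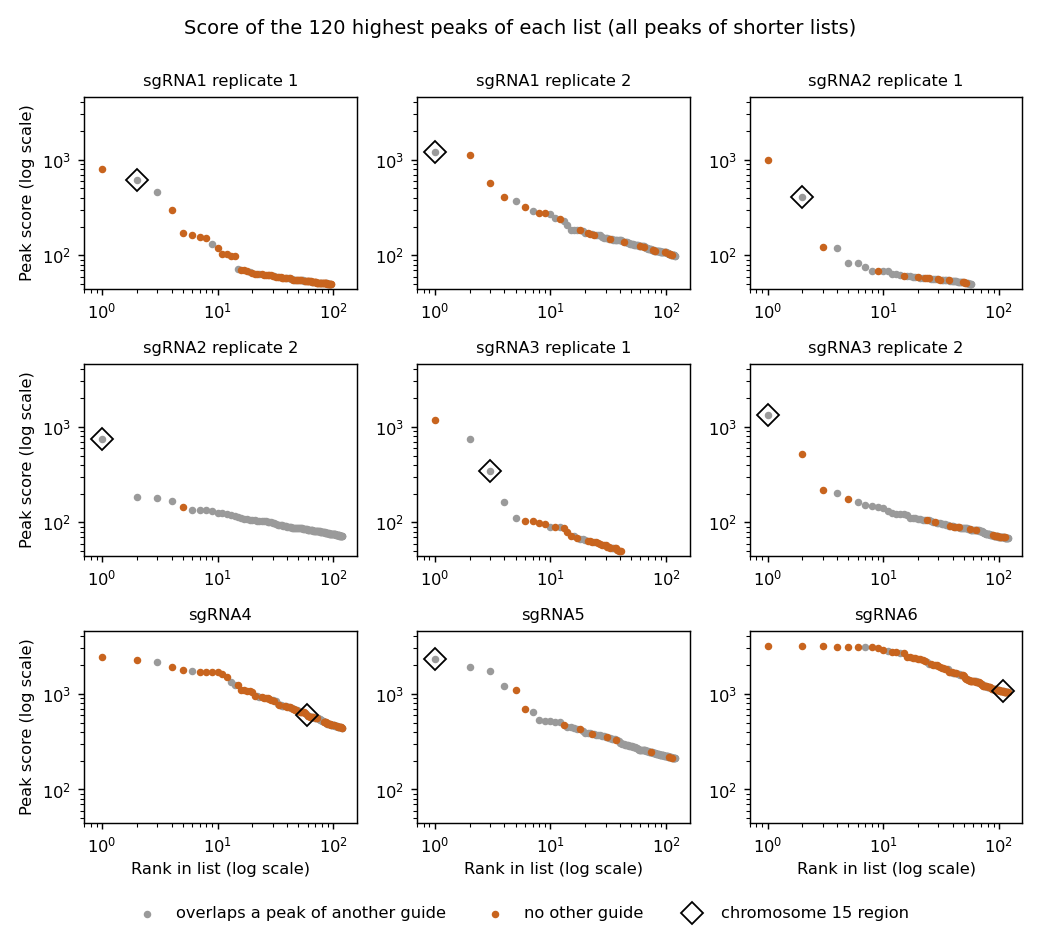
Score (log axis) against rank (log axis) for the 120 highest peaks of each of the 9 lists, or all peaks of shorter lists, 1 point per peak. Orange peaks overlap no peak of another guide, grey peaks do, and the diamond marks the chromosome 15 region, which ranks between 1 and 3 in 7 lists, 59 with sgRNA4 and 109 with sgRNA6.

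Replicates of a guide shared far more peaks than random placement gave. For sgRNA1, 35 of 96 replicate 1 peaks (36.5%, 95% interval 26.9 to 46.9) overlapped a replicate 2 peak, for sgRNA2 16 of 58 (27.6%, 16.7 to 40.9), and for sgRNA3 17 of 41 (41.5%, 26.3 to 57.9). Random placement gave means of 0.063, 0.017 and 0.006 peaks (placement permutation test, p = 0.000999 for each, the smallest the placements can give). From the side of the longer lists, 2.74% of sgRNA1, 2.81% of sgRNA2 and 4.45% of sgRNA3 replicate 2 peaks had a counterpart in replicate 1.

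For sgRNA1 and sgRNA3, overlap with the guide's own replicate 2 list exceeded that with the replicate 2 lists of the other replicated guides. Replicate 1 peaks of sgRNA1 overlapped the replicate 2 lists of sgRNA2 in 2 of 96 cases and of sgRNA3 in 3 of 96 (Fisher's exact test against the 35 in its own list, adjusted p = 1.99e-09 and 7.79e-09). Of the 35 sgRNA1 peaks in both replicates, 11 overlapped a peak of any other guide, as did 6 of the 17 for sgRNA3. Replicate 1 peaks of sgRNA3 overlapped the lists of sgRNA1 and sgRNA2 in 1 of 41 cases each, against 17 in its own (Fisher's exact test, adjusted p = 3.29e-05 for both). For sgRNA2, no such difference was detected: its replicate 1 peaks overlapped the sgRNA1 list in 13 of 58 cases (22.4%, adjusted p = 0.669) and the sgRNA3 list in 10 of 58 (17.2%, adjusted p = 0.319), against 16 in its own (Fisher's exact test). These tests did not adjust for the length of the replicate 2 lists, of 1278, 570 and 382 peaks for sgRNA1, sgRNA2 and sgRNA3. A longer list can be overlapped more often, which favours the own list for sgRNA1 but not for sgRNA3. Both counts of a test came from the same replicate 1 peaks. The exact McNemar test, made for such pairs, gave the same calls. The sgRNA2 replicate 1 list also overlapped the long lists more than the other replicate 1 lists did: 51.7% of its peaks were found with sgRNA4, 58.6% with sgRNA5 and 67.2% with sgRNA6. The corresponding shares were 13.5, 12.5 and 15.6% for sgRNA1 and 19.5, 12.2 and 14.6% for sgRNA3.

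**Figure D3:**
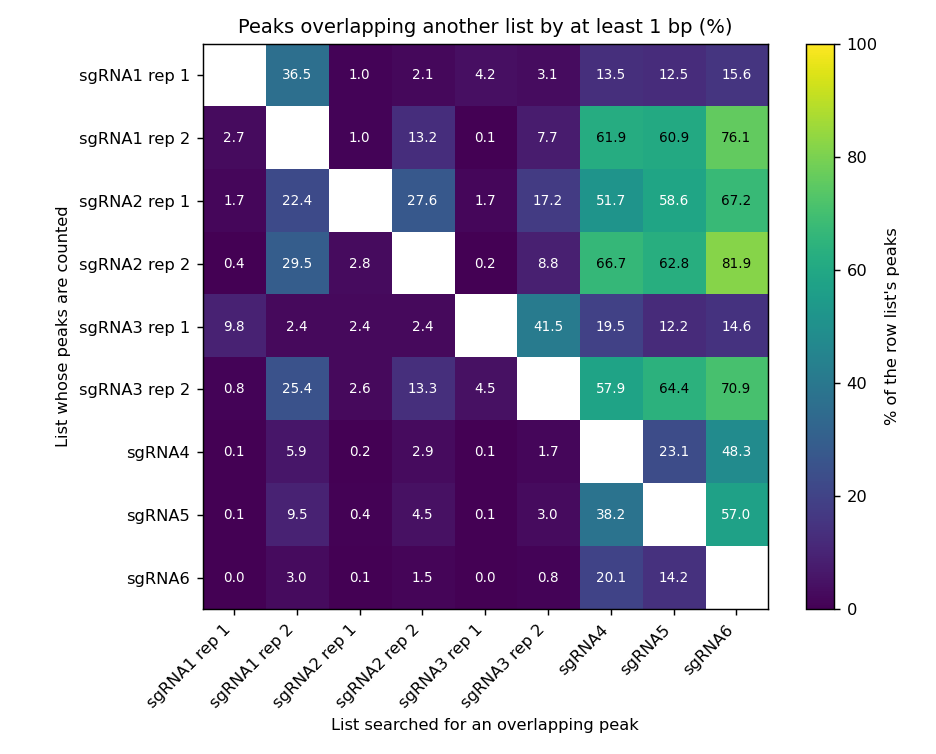
Percentage of the peaks of each list (vertical axis) that overlap a peak of each other list (horizontal axis) by at least 1 bp, in % of the vertical axis list, for all pairs of the 9 lists. Replicate 1 of sgRNA1 and sgRNA3 overlaps its own replicate 2 list most (36.5 and 41.5%), whereas sgRNA2 replicate 1 overlaps the sgRNA6 list most (67.2%).

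Many regions held peaks with more than 1 guide. Such sharing does not tell binding from background pull-down that does not depend on the guide, as the library without sgRNA was not analysed here. After merging replicates, 84.6% of 1339 sgRNA1 peaks (95% interval 82.6 to 86.5), 92.2% of 612 sgRNA2 peaks (89.7 to 94.2), 78.6% of 406 sgRNA3 peaks (74.3 to 82.5), 53.1% of 13660 sgRNA4 peaks (52.2 to 53.9), 65.1% of 8346 sgRNA5 peaks (64.1 to 66.1) and 27.1% of 33611 sgRNA6 peaks (26.6 to 27.6) overlapped a peak of another guide. Random placement gave 2.82, 2.93, 2.73, 2.65, 2.63 and 1.35%, so that the observed shares were 20 to 31.5 times those of chance (placement permutation test, p = 0.000999 for each, the smallest the placements can give). A share also depends on list length, as the longest list, that of sgRNA6, was searched against the fewest peaks of other guides. The shares therefore do not rank the guides. All 15 pairs of guides overlapped beyond random placement, by 20.2 to 296 times (placement permutation test, adjusted p = 0.000999 for each). Against random shifts of 10 to 50 kb, a stricter comparison chosen after the data were seen, the shares were 7.13 to 13.9 times and the overlaps of pairs 7.10 to 140 times those of chance. The high shares of sgRNA1 and sgRNA3 rested on replicate 2: without it, 25% of sgRNA1, 74.1% of sgRNA2 and 31.7% of sgRNA3 peaks were shared. Without replicate 2, whose lists were longer, sgRNA1 and sgRNA2 shared 1 peak, sgRNA2 and sgRNA3 1 and sgRNA1 and sgRNA3 4. These overlaps were still beyond random placement (permutation test, adjusted p = 0.00300, 0.00214 and 0.00115). The single shared peaks were the chromosome 15 region alone. The 4 included it and a region on chromosome 14 at 20811329 to 20812012, so these p-values rest on few regions. Among peaks found in both replicates each of these pairs again shared 1, the chromosome 15 region.

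Of 43438 merged regions, 34165 (78.7%) were found with 1 guide, 6100 with 2, 2333 with 3, 632 with 4, 182 with 5 and 26 with all 6. Of those found with 1 guide, 24499 were sgRNA6 peaks and 6413 sgRNA4 peaks, from 1 library each. The 78.7% therefore depends mostly on the longest lists and does not describe each guide. Besides the region on chromosome 15, the regions found with all 6 guides at the best mean rank lay on chromosome 17 at 19551005 to 19552773, chromosome 1 at 144930545 to 144933159, chromosome 13 at 88323089 to 88326485, chromosome 17 at 39843858 to 39846282 and chromosome 1 at 85741505 to 85742818. These were followed by regions on chromosome 10 at 46951170 to 46952181, chromosome 9 at 66492846 to 66494922, chromosome 6 at 131948856 to 131949904 and chromosome 5 at 89769015 to 89770974. Mean ranks here combine lists of 41 to 33611 peaks, so this order does not compare heights between guides.

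Peaks were unevenly spread over the chromosomes. With sgRNA4, sgRNA5 and sgRNA6, chromosome 19 held 3.97, 3.35 and 3.47 times, chromosome 17 held 3.16, 2.81 and 2.89 times, and chromosome 22 held 2.48, 1.90 and 2.36 times as many peaks as its length would give. Chromosome 4 held 0.450, 0.466 and 0.452 times its share with the same guides. In the replicate 2 lists, chromosome 1 was raised 2.12 times for sgRNA1, 2.11 times for sgRNA2 and 2.49 times for sgRNA3, and chromosome X held 0.368, 0.138 and 0.410 times its share.

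The departure from chromosome length passed the simulated exact chi-square test in the 3 replicate 2 lists and with sgRNA4, sgRNA5 and sgRNA6 (p = 1e-05 for each, the smallest the draws can give) and in sgRNA1 replicate 1 (p = 0.0110), where chromosome 13 held 12 of 96 peaks, 3.30 times its share. By the same simulated exact test, it was not detected among the 58 peaks of sgRNA2 replicate 1 (p = 0.305) or the 41 of sgRNA3 replicate 1 (p = 0.578). Restricted to peaks found with no other guide, the sgRNA2 call changed in both replicates: the simulated exact p was 0.0171 over 15 peaks in replicate 1 and 0.184 over 34 peaks in replicate 2.

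**Figure D4:**
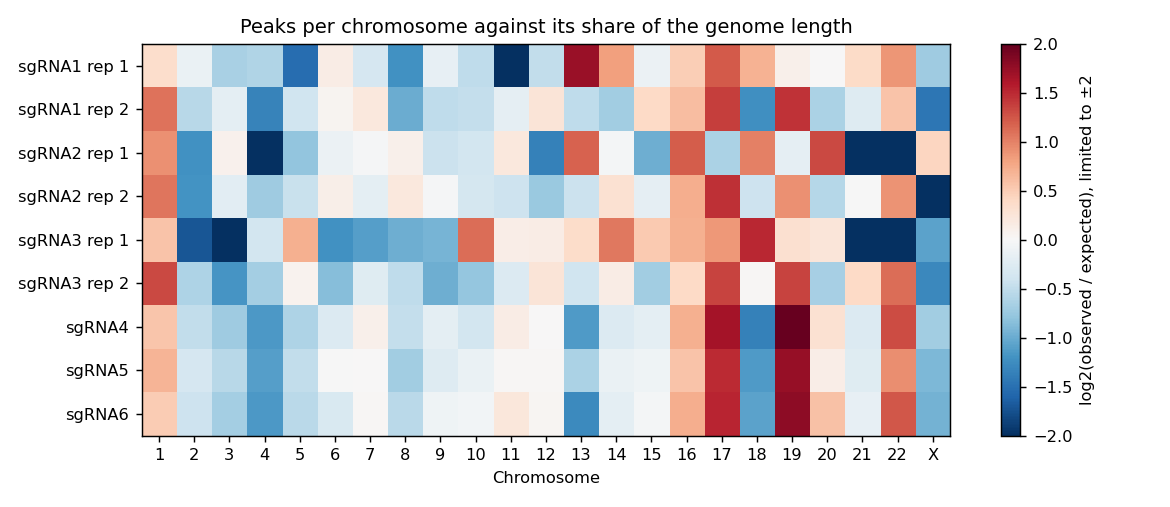
Observed over expected number of peaks on each chromosome, as log2 limited to ±2, for the 9 lists, with expectation set by chromosome length; chromosome Y was left out. Chromosomes 17 and 19 are raised in all 3 replicate 2 lists and with sgRNA4, sgRNA5 and sgRNA6, by 2.54 to 3.16 and 1.89 to 3.97 times.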

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

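The tests in this part of the sgRNA2 overlap were chosen only after that overlap had been seen.

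For each replicated guide, the share of replicate 1 peaks found in its own replicate 2 list was set against the share found in the sgRNA6 list. The difference was 20.8 percentage points for sgRNA1 and 26.8 for sgRNA3, but -39.7 for sgRNA2. Counting peaks found in 1 of the 2 lists alone, 24 sgRNA1 peaks were in the own list and 4 in that of sgRNA6, against 1 and 24 for sgRNA2 and 14 and 3 for sgRNA3. The test follows the overlap with sgRNA6 that prompted it and takes peaks of 1 library per guide as units, so it compares these lists and not the guides. The lists differed by Fisher's exact test between sgRNA1 and sgRNA2 (adjusted p = 2.09e-09) and between sgRNA2 and sgRNA3 (adjusted p = 2.6e-07). Between sgRNA1 and sgRNA3 no difference was detected by the same exact test (adjusted p = 1).

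The overlap of sgRNA2 replicate 1 with lists of other guides was set against 2 technical explanations. A library mislabelled with another guide of the series was argued against by its highest peak, on chromosome 5, which was also in the sgRNA2 replicate 2 list and in 0 lists of other guides. List length was argued against by the other replicate 1 lists, of 96 and 41 peaks, whose overlap with sgRNA6 differed by only 0.991 points. More pull-down of regions that do not depend on the guide in this 1 library stays open, as does a real property of sgRNA2, and neither was tested.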

How the results depend on the processing

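Random shifts, placement in 1 Mb bins, the McNemar test, the sgRNA1 to sgRNA3 count ratio and stricter settings for own against other lists were chosen only after results were seen. Of 268 alternative values for 89 results, 245 were counted as unchanged and 23 were not. Peak width apart, unchanged meant the same direction and side of the threshold, or, without a test, a value within a set limit. Large changes in size could thus count as unchanged, as for shared sgRNA1 peaks, 84.6% in the main setting and 25% without replicate 2. Pairs among sgRNA4, sgRNA5 and sgRNA6, which have no replicates, could not change under the replicate settings. With peak width in place of score, the ratio of the widest peak to the median was 2.62 and 8.35 (sgRNA1 replicates 1 and 2), 4.08 and 3.45 (sgRNA2), 2.08 and 3.87 (sgRNA3), and 9.58, 10.2 and 10.9 (sgRNA4, sgRNA5, sgRNA6). All 9 were counted as changed whatever their value, with no limit applied. A width ratio is a different measure from a score ratio, so these values show no change in a result. With only unshared peaks, the simulated exact chromosome test reached p = 0.0171 in sgRNA2 replicate 1 and lost its call in replicate 2 (p = 0.184), where 34 of 570 peaks were left. In replicate 1, 4 of the 15 unshared peaks lay on chromosome 13, which makes up 3.79% of the length, between 64434121 and 91280891. Why they lay there was not tested. The other 12 changes concern how many other guides hold a named region: 7 with at least 50% overlap of both peaks, where the chromosome 15 region, counted from the sgRNA1 or sgRNA5 peak, kept 4 other guides, and 5 with the 50% of each list that scored higher. No other guide (0) was left under 1 or both at the sgRNA3 peaks on chromosome 4, the sgRNA4 peak on chromosome 5, the sgRNA5 peak on chromosome 14 at 105742053 and the sgRNA6 peak on chromosome 15, and 1 was left at the sgRNA2 peak on chromosome 14.

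With the replicate number as a replicate block, the difference in peak number gave p = 0.167 by exact permutation, the smallest that its 6 arrangements allow. Correlations between same-numbered libraries' deviations in shares of peaks over 2687 bins of 1 Mb were 0.0442, 0.163 and 0.0525. The numbers were therefore not taken to pair the libraries, but shares cannot show a common difference in list length. All 3 replicate 2 lists were 9.32 to 13.3 times longer than replicate 1, so the test without a block does not settle whether the guides differ. The sgRNA1 to sgRNA3 count ratio was 2.80, and 2.34 to 3.35 with 1 replicate left out. Not run: every planned seed, adjacent motif, match length, promoter and gene list alternative, which need a genome or annotation of this build, and the higher-scoring fractions for peak number, which fix their own outcome. Unknown depth limits every comparison of peak numbers.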

Other observations

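All tests in this part were chosen after the results they bear on had been seen, except the split of replicate 2 peaks by presence in replicate 1; the overall sharing of those lists had been seen before it.

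With sgRNA4 and sgRNA6, peaks found with no other guide were more frequent among the 20 highest peaks than in the upper middle of the list. With sgRNA4, 16 of the 20 highest peaks (80%, 95% interval 56.3 to 94.3) overlapped no other guide's peak, against 29.0% at ranks 501 to 2000 and 53.9% from rank 5001 on. With sgRNA6 the shares were 17 of 20 (85%, 62.1 to 96.8), 40.1% and 77.3%. With sgRNA5 they were 4 of 20 (20%, 5.73 to 43.7), 15.5% and 49.2%. Ranks 1 to 20 differed from ranks 501 to 2000 for sgRNA4 (Fisher's exact test, adjusted p = 1.22e-05) and sgRNA6 (adjusted p = 0.000124), and no difference was detected for sgRNA5 (adjusted p = 0.536). The top was not tested against the lower end of the lists.

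Peaks within 5 Mb of a chromosome end made up 19.6% of the sgRNA4 list, 20% of the sgRNA6 list and 12.9% of the sgRNA5 list, against 9.50, 9.47 and 9.06% with random placement (permutation test, p = 0.000999 for each, the smallest the placements can give). Among the 100 highest peaks the shares were 38, 39 and 12%. The share also passed the permutation test in sgRNA1 replicate 2 (11.4%, p = 0.000999), sgRNA2 replicate 2 (11.6%, p = 0.00799) and sgRNA3 replicate 1 (24.4%, p = 0.002). It did not in sgRNA1 replicate 1 (13.5%, permutation p = 0.0609), sgRNA2 replicate 1 (6.90%, below the 8.42% of random placement, p = 0.74) or sgRNA3 replicate 2 (10.5%, p = 0.134). All 12 chromosome 13 peaks of sgRNA1 replicate 1 lay between 64434121 and 91280891. This stretch held 12.5, 6.90 and 4.88% of the replicate 1 lists of sgRNA1, sgRNA2 and sgRNA3 (12, 4 and 2 peaks, of which 10, 4 and 2 were found with no other guide), but 1.1, 1.4 and 1.83% of their replicate 2 lists, a difference that was not tested. Chromosome Y held 42 peaks, 5 with sgRNA4, 1 with sgRNA5 and 36 with sgRNA6, none starting beyond 2.60 Mb, and 22 of them had a peak of the same list 50 kb further along on chromosome X, within 500 bp. The tips of the X and Y short arms carry the same sequence, so the lists cannot tell a Y peak there from an X peak.

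Among replicate 1 peaks missing from their own replicate 2 list, the highest of both sgRNA1 (score 457, rank 3 of 96) and sgRNA3 (745, rank 2 of 41) was a single region on chromosome 14 at 20811329 to 20812012. It was also found with sgRNA5 (rank 1758) and sgRNA6 (rank 2408), in no replicate 2 list and not in sgRNA2 replicate 1. For sgRNA2, the highest such peak ranked 3 of 58, on chromosome 1 at 12215050 to 12215714, and was in no other list.

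The chromosome 15 region, the only one found in all 9 lists, was set against 207 other regions found with at least 5 guides, in the 6 lists that held a peak at 100 or more of them. It outranked all of those held in 4 lists, and 2 of 205 ranked above it with sgRNA4 and 7 of 206 with sgRNA6, but a region picked for its presence in the 3 short replicate 1 lists is a high one by that choice, so these ranks test no explanation. A candidate explanation is a copy of this stretch on the transfected plasmids, from which reads would map to the genome whatever the guide. The centres of its 9 peaks lay within 362 bp, but the median spread of the other shared regions was 380 bp, so this measure cannot tell a plasmid copy from a genomic region; the chromosome 14 region at 20811329 was not tested for it. A background region of the cells stays open too, as the library without sgRNA was not analysed here.

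The length of the replicate 2 lists may come from added peaks of low score at regions also found with other guides. Of the peaks missing from replicate 1, 89.2% (sgRNA1) and 83.8% (sgRNA3) overlapped another guide's peak, against 31.4 and 35.3% of those in both replicates (Fisher's exact test, p = 4.05e-15 and 1.89e-05). For sgRNA2 the shares were 94.0 and 93.8% (Fisher's exact test, p = 1), with 16 peaks in both replicates. Its added peaks thus also lay mostly at regions found with other guides, but no difference from the peaks in both was detected. Median scores of the added peaks were 63.6, 59.3 and 60.4 for sgRNA1, sgRNA2 and sgRNA3, against 123, 80.7 and 88.4 for peaks in both (permutation test, p = 0.0001 each, the smallest that 10000 permutations give). Peaks that recur in a much shorter list tend to be the higher ones under any explanation, so this score difference cannot tell explanations apart. A deeper replicate 2 library would give the same picture and cannot be examined without read counts.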
